A study of Homo sapiens with 6 samples.

How the data were processed

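Messenger RNA was sequenced from 786-O cells, an established human renal cell carcinoma line, in 2 groups of 3 libraries: cells with a control short hairpin RNA (sh-Control) and cells with a short hairpin RNA against CBX7 (sh-CBX7). Per the labels' protocols, RNA was selected with poly-T beads and made into libraries with a directional kit. The deposited table holds read counts for 58735 genes in 6 libraries, as whole numbers without normalization. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used; the notes give neither their order nor the strand setting of the counting. Reads of overlapping and antisense genes could therefore not be told apart here. Those notes name the build hg19, while the gene coordinates in the deposited count table had the start and end of GENCODE 29 on GRCh38 for 58724 of 58735 genes (99.98%), so positions are given on GRCh38. The columns of the deposited count table call the target libraries siCBX7, whereas the labels call them sh-CBX7; columns were matched to libraries by target and replicate number, and the labels' name is used.

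Total counts ran from 16384151 to 18868874 per library. The filter filterByExpr of edgeR 4.0.16 (R 4.3.3) left 14573 genes, which were normalised with TMM and compared with the quasi-likelihood test (glmQLFit and glmQLFTest) in an unpaired fit. P-values were adjusted with the Benjamini-Hochberg method and called below 0.05; the standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM values are TMM-normalised counts scaled to the library size, given as mean ± SD over the 3 libraries of a group. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within a group, log2 CPM values of library pairs correlated at 0.990 to 0.992 across genes, which are not independent replicates. The chi-square per gene between libraries of a group was 2.84 to 9.31 over genes with at least 20 counts per pair, above sampling noise in each pair, so each library was kept as a separate sample. The highest values, 9.31 and 5.81, were those of sh-Control replicate 1 with sh-Control replicates 2 and 3.

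The genes named in the text follow a rule fixed before the data were examined. It takes CBX7 as the targeted gene and RNF26 as a gene of the series title. It then takes the 12 protein-coding genes with the largest change in each direction among called genes with a mean of at least 1 CPM and groups that do not overlap. Last, it takes up to 4 tested members of each of 31 fixed lists by smallest p. Some genes that the rule takes are not reported here, and genes outside the rule are marked where they appear. Lists with at least 5 tested members (30 of 31) were tested with camera (limma 3.58.1) on log2 CPM values with a prior count of 2 and a preset correlation of 0.01, and adjusted over those 30 lists. Only the interferon list kept its call with an estimated correlation. The lists covered TNF and NF-kB targets, TNF signalling components, Polycomb subunits, HOX genes, developmental transcription factors, the cell cycle, CDK inhibitors, p53 targets, apoptosis, HIF targets, tyrosine kinase inhibitor targets, interferon response, matrix, TGF-beta, immediate early genes, metabolism, stress responses, translation, mitochondria, histones, MYC targets, and markers of kidney epithelium, immune, endothelial and fibroblast cells.

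Before use, the tests were tested on simulated data drawn for the same 14573 genes and 6 libraries. The edgeR test called 72% of 100 genes changed by 0.5 and 87% of 100 genes changed by 1 on the log2 scale, and 0.09% of 14333 unchanged genes. Nearly all simulated genes were thus unchanged, so these rates need not hold for the real data, where 53.3% of tested genes were called. The alternatives chosen before the data were examined were DESeq2 size factors, library size alone, no low count filter, a CPM filter, DESeq2 1.42.0, limma voom, a minimum log2 fold change of 1, the replicate number as a block, leaving out each library, an estimated correlation, and fry. Upper quartile normalization, a correction for transcript length and GC content, and list tests without genes that hold a 7-base motif were added after seeing the data.

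Transcript sequences came from GENCODE 29, with 1 coding transcript for each of 12436 tested genes (85.3%). For each 7-base sequence in 3' UTRs of at least 50 bases, genes with a mean of at least 5 CPM were compared by log2 fold change after a fit on 3' UTR length and GC content, over 10067 genes. Sequences held by at least 20 genes were ranked. The z of a sequence is the summed deviation of its genes from the mean of all genes, in units of its standard error, with residuals limited to 2 in size. For differences between genes with and without a sequence, the SE was taken over genes as if independent, not between libraries. The 6-, 7- and 8-base sequences of 3' UTRs, coding sequences and whole transcripts were all looked at. In simulated data, 5 of 5 planted 7-base effects came out at rank 1. For CBX7, each 16-base window of its 4081-base transcript was compared with other transcripts at up to 2 mismatches, and windows were ranked by the mean log2 fold change of the matching genes, and also by that mean weighted for the number of genes. Of 5 windows with a planted change in simulated data, the worst came out at rank 23 of 4012.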

Results

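The data were read counts per gene in 6 libraries of 786-O cells, 3 with the control hairpin and 3 with the hairpin against CBX7. CBX7 is a chromobox protein of Polycomb repressive complexes. The series title names CBX7 with RNF26, TNF signalling, proliferation and sensitivity to tyrosine kinase inhibitors in clear cell renal cell carcinoma. The sh-Control libraries held 16961808, 18006814 and 16384151 counts and the sh-CBX7 libraries 18868874, 16473407 and 17668422. The first principal component took 71.7% of the variance and separated the groups.

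CBX7 itself (ENSG00000100307; GRCh38 chromosome 22, 39120167 to 39152674, minus strand) had 203, 240 and 183 counts in the sh-Control libraries and 143, 111 and 142 counts in the sh-CBX7 libraries. Its level fell from 12.2 ± 0.98 to 7.44 ± 0.67 CPM (SD, n = 3 per group), a log2 fold change of -0.71 (SE 0.13, edgeR adjusted p = 5.41e-05). The transcript was thus 1.64-fold lower in sh-CBX7 and still detected in each library. RNF26, a RING finger gene, fell from 100.5 ± 10.9 to 54.8 ± 2.20 CPM (log2 fold change -0.88, SE 0.07, edgeR adjusted p = 1.22e-09).

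**Figure D1:**
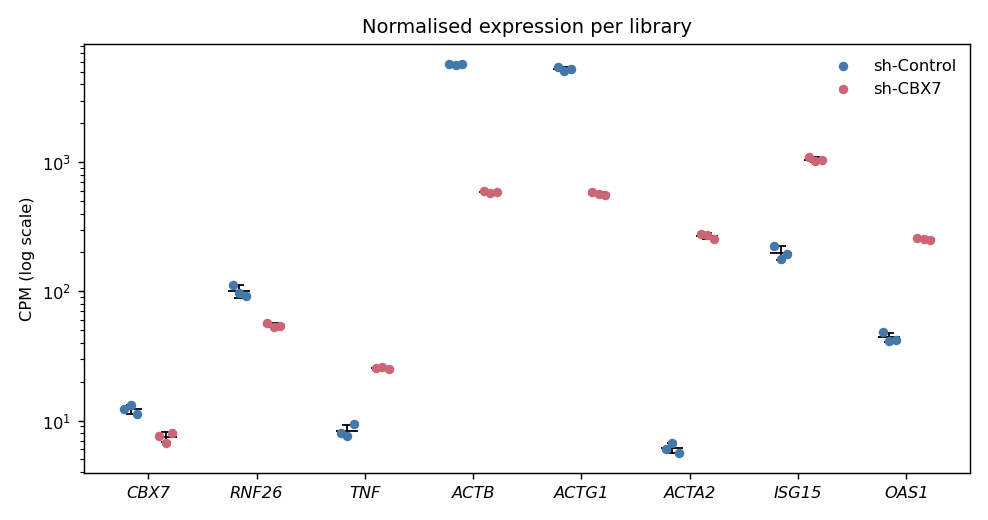
Normalised expression (CPM, log scale) of 8 genes in each library; points are libraries, horizontal marks the mean and bars the SD of 3 libraries per group. CBX7 fell from 12.2 to 7.44 CPM, while ACTB fell from 5721 to 587.5 CPM and ACTA2 rose from 6.14 to 268.5 CPM.

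What differed between cells with the CBX7 hairpin and control cells was asked across all genes. Of 14573 tested genes 7766 (53.3%) changed in the edgeR test, 3799 being higher and 3967 lower in sh-CBX7. Interferon response, TNF and NF-kB target and matrix genes rose as lists, whereas ribosomal protein, G1/S, G2/M and cholesterol synthesis genes fell, as did the cytoplasmic actin genes. With an estimated correlation only the interferon list kept its call (camera adjusted p = 0.00785); for the other lists of that sentence the adjusted p ran from 0.0732 to 0.114. Of the called genes, 762 rose and 481 fell by at least 1 on the log2 scale. The groups did not overlap for 8591 genes, 59% of those tested, where chance gives 10%.

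The largest rise among the named genes was that of ACTA2, the smooth muscle actin gene, from 6.14 ± 0.57 to 268.5 ± 13.5 CPM (SD, n = 3 per group; log2 fold change 5.45, SE 0.08, edgeR adjusted p = 1.57e-22). TNFSF15, a TNF superfamily ligand, rose by 4.35 on the log2 scale, CD69 by 3.94, the chemokine receptor CCR1 by 3.87, the chemokine CXCL11 by 3.33 and the galectin LGALS9 by 3.26. IFITM1, an interferon-induced membrane protein, rose from 6.46 to 88.1 CPM. The growth factor FGF1 rose by 3.72, the ubiquitin ligase NEURL3 by 3.48, NHSL2 by 3.87, the adhesion molecule CNTN6 by 3.31 and the nuclear receptor NR5A2 by 3.30. TNFSF15, CCR1, NHSL2, FGF1, CNTN6 and NR5A2 lay below 1 CPM in sh-Control, so their folds are less precise, with SE from 0.25 to 0.44.

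The cytoplasmic actins were among the genes that fell furthest. ACTB went from 5721 ± 86.0 to 587.5 ± 10.005 CPM (SD, n = 3 per group; log2 fold change -3.28, SE 0.05, edgeR adjusted p = 1.57e-22) and ACTG1 from 5268 ± 171 to 569.8 ± 15.0 CPM (-3.21, SE 0.05). Together they took 1.09% of all counts in sh-Control and 0.12% in sh-CBX7. The early response transcription factor EGR1 had a log2 fold change of -3.39, EDN2 -3.22, the vesicle transport gene SEC22A -2.83, the secreted glycoprotein LGALS3BP -2.81, the ubiquitin ligase HECTD3 -2.79 and the splicing factor SNRPC -2.73. PRSS35 (-2.61), FLG (-2.60), the claudin CLDN2 (-2.51) and the galactosyltransferase B4GALT1 (-2.48) completed the 12. EDN2, PRSS35 and EGR1 lay below 1 CPM in sh-CBX7, so their folds are less precise, with SE of 0.45, 0.34 and 0.22. SEC22A holds a 16-base stretch identical to CBX7 coding sequence, and ACTB, ACTG1, LGALS3BP and HECTD3 hold the same stretch with 2 mismatches. Reads of ACTB and ACTG1 can be split between these similar genes and their processed copies, which was not measured here.

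**Figure D2:**
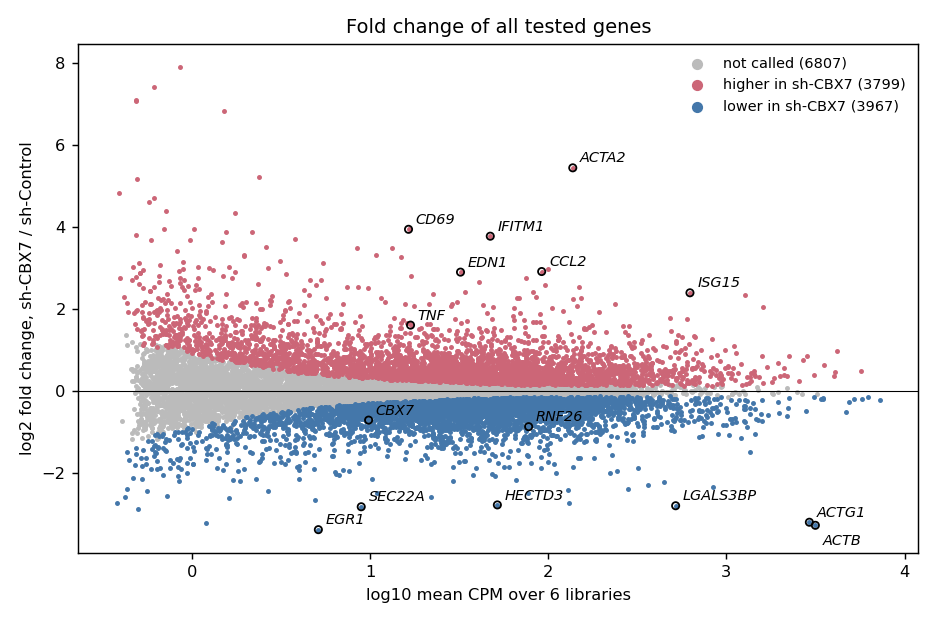
Log2 fold change (sh-CBX7 over sh-Control) against log10 mean CPM over 6 libraries for the 14573 tested genes; red points were called higher (3799), blue lower (3967) and grey not called, and circles mark labelled genes. ACTA2 (5.45) stands highest among the labelled genes, and ACTB (-3.28) and ACTG1 (-3.21) lie at the bottom among the most abundant transcripts.

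TNF signalling is named in the series title. Of 46 tested TNF and NF-kB target genes, 34 rose, 8 fell and 4 were not called (35 and 8 when adjusted over the list alone). The list rose as a group, with a median log2 fold change of 0.67 and a camera adjusted p = 2.96e-07, which was adjusted p = 0.0888 with an estimated correlation. The chemokine CCL2 rose from 21.5 ± 1.36 to 162.3 ± 6.76 CPM (SD, n = 3 per group; log2 fold change 2.91), the peptide hormone EDN1 by 2.90, the protease PLAU by 1.43 and the adhesion molecule ICAM1 by 1.24. TNF itself, chosen after its value was seen, rose from 8.36 ± 0.96 to 25.4 ± 0.42 CPM (log2 fold change 1.60, SE 0.11, edgeR adjusted p = 4.24e-11). Among 49 components of TNF signalling, 15 rose and 10 fell (camera adjusted p = 0.336); MAPK11 had a log2 fold change of 0.77, TRADD 0.71 and MAPK3 -0.70.

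Interferon response genes had the highest median log2 fold change of the tested lists, 1.39, and 50 of 53 rose while 1 fell (camera adjusted p = 1.85e-21; adjusted p = 0.00785 with an estimated correlation). OAS1, an antiviral RNA sensor, rose from 44.0 ± 3.76 to 254.5 ± 3.96 CPM (SD, n = 3 per group; log2 fold change 2.53, SE 0.07). ISG15, a ubiquitin-like modifier, rose from 199.6 ± 24.3 to 1049 ± 39.3 CPM (2.39), and IFI27 by 2.13. Reads of closely related members such as the IFITM and HLA genes can be split between copies.

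Mesenchymal and matrix genes rose as a list, with 33 of 48 higher and 5 lower (34 and 5 when adjusted over the list alone; median 0.38, camera adjusted p = 2.31e-05; adjusted p = 0.0732 with an estimated correlation). TNC, a matrix glycoprotein, had a log2 fold change of 1.44, the integrin ITGA5 1.14 and the laminin chain LAMB3 1.09. Immediate early genes rose in 23 of 32 and fell in 3 (median 0.57, camera adjusted p = 1.31e-05; adjusted p = 0.113 with an estimated correlation); the phosphatase DUSP5 rose by 1.16, DUSP6 by 1.09 and the stress factor ATF3 by 1.27, against the fall of EGR1. Of 31 HIF targets, 16 rose and 5 fell (median 0.28, camera adjusted p = 0.00485; adjusted p = 0.0888 with an estimated correlation), with ANGPTL4 at 2.27, ADM at 1.37 and the carbonic anhydrase CA12 at -1.22.

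Stress lists moved in both directions. Amino acid stress genes rose in 17 of 27 and fell in 4 (median 0.38, camera adjusted p = 0.00485; adjusted p = 0.113 with an estimated correlation), with NUPR1 at 1.57, DDIT3 at 1.53, TRIB3 at 0.90 and the transporter SLC7A5 at -0.62. Unfolded protein response genes rose in 14 of 22 and fell in 2 (median 0.23, camera adjusted p = 0.00647; adjusted p = 0.101 with an estimated correlation), with PPP1R15A at 1.21, CALR at 0.84, HERPUD1 at 0.69 and the chaperone HYOU1 at -1.13. Heat shock genes fell in 9 of 14 and rose in 3 (median -0.65, camera adjusted p = 0.00887; adjusted p = 0.113 with an estimated correlation). The cytosolic chaperone HSP90AA1 had a log2 fold change of -1.06, HSPD1 -0.97, HSPA8 -0.74 and HSP90AB1 -0.62.

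Nearly all ribosomal protein genes fell: 72 of 75 were lower and 0 higher in the edgeR test, with a median log2 fold change of -0.60 (camera adjusted p = 3.67e-19; adjusted p = 0.114 with an estimated correlation). Their share of all counts was 7.75% ± 0.19 in sh-Control and 5.21% ± 0.10 in sh-CBX7 (SD, n = 3 per group). RPSA fell from 2003 ± 91.6 to 709.7 ± 25.9 CPM (log2 fold change -1.497), and RPL4 and RPL3 had log2 fold changes of -1.16 and -1.06. Reads of these genes can also be counted for processed pseudogenes, which was not measured here. MYC target genes fell in 21 of 28 and rose in 3 (median -0.30, camera adjusted p = 0.000591; adjusted p = 0.0825 with an estimated correlation); PA2G4 had -0.82 and nucleolin, NCL, -0.61, while NOLC1 had 1.05. Oxidative phosphorylation genes fell in 26 of 41 and rose in 2 (27 and 2 when adjusted over the list alone; median -0.29, camera adjusted p = 3.91e-05; adjusted p = 0.215 with an estimated correlation), led by the succinate dehydrogenase subunit SDHD at -1.89 and by ATP5F1B at -0.80, ATP5F1A at -0.69 and UQCRC1 at -0.63.

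Proliferation is also named in the series title. G1/S and DNA replication genes fell in 42 of 57 and rose in 1 (median -0.42, camera adjusted p = 3.41e-08; adjusted p = 0.0732 with an estimated correlation). The thymidine kinase TK1 fell from 339.0 ± 31.5 to 114.2 ± 4.06 CPM (SD, n = 3 per group; log2 fold change -1.57), and the replicative helicase subunits MCM6, MCM2 and MCM4 had -1.11, -0.89 and -0.77. G2/M and mitosis genes fell in 46 of 57 and rose in 2 (47 and 2 when adjusted over the list alone; median -0.41, camera adjusted p = 1.86e-09; adjusted p = 0.085 with an estimated correlation), among them ESPL1 at -1.52, KIF4A at -1.45, TOP2A at -1.14 and CDC20 at -0.89. The CDK inhibitor CDKN1A rose from 141.9 ± 13.5 to 427.9 ± 10.3 CPM (log2 fold change 1.59), CDKN2D had 0.82 and CDKN1B 0.43, while CDKN3, a phosphatase, had -0.67. The 6 tested CDK inhibitors split 3 and 3 (camera adjusted p = 0.662). Cholesterol synthesis genes fell in 19 of 25 and rose in 3 (median -0.52, camera adjusted p = 0.000105; adjusted p = 0.0732 with an estimated correlation), with DHCR7 at -1.19, IDI1 at -0.97, MSMO1 at -0.74 and the sterol sensor INSIG1 at 0.88.

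**Figure D3:**
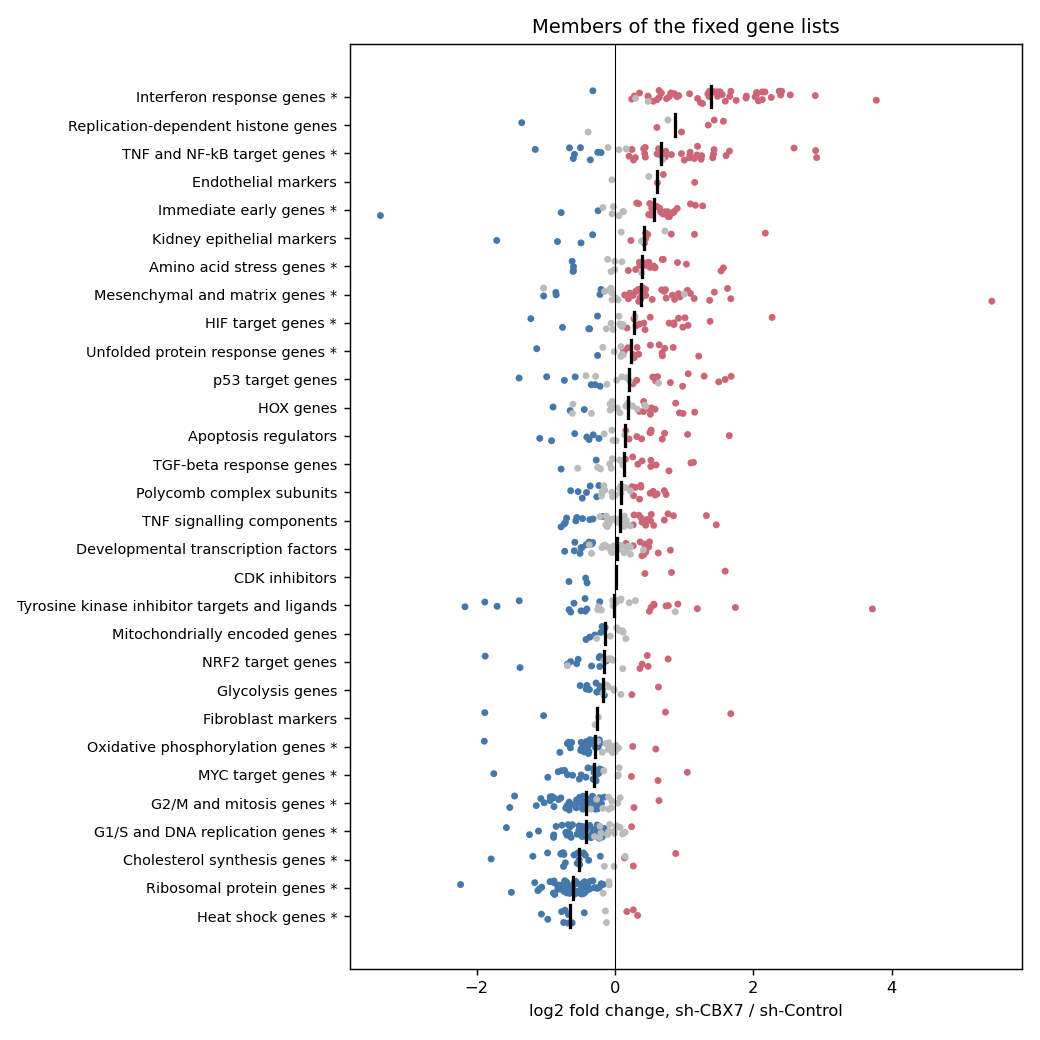
Log2 fold change (sh-CBX7 over sh-Control) of each tested member of the 30 tested lists; red and blue points were called higher and lower, grey points not called, black lines mark medians and asterisks a camera adjusted p under 0.05. Medians run from 1.39 for interferon response genes to -0.65 for heat shock genes.

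Sensitivity to tyrosine kinase inhibitors, the last subject of the title, was not measured, but 35 targets and ligands of such drugs were. Of these 10 rose and 12 fell (camera adjusted p = 0.971), with a median of -0.015 and a mean of 0.029, which differ in sign. The ligand HBEGF had a log2 fold change of 1.74, PGF 0.91 and the receptor FGFR4 -1.38. Polycomb target classes were examined because CBX7 is a Polycomb subunit. HOX genes rose in 11 of 31 and fell in 3 (camera adjusted p = 0.0669), with HOXC6 at 1.15, HOXB7 at 0.98, HOXA9 at 0.93 and HOXA3 at -0.89. Developmental transcription factors split 12 higher and 10 lower of 42 (camera adjusted p = 0.722), with SOX9 at 0.80 and PAX8 at -0.32. Among 31 other Polycomb subunits, 12 rose and 7 fell (camera adjusted p = 0.354), with RBBP4 at 0.74, CBX6 at -0.53 and PHF19 at -0.64.

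None of the next 8 lists passed the test over all tested genes and 6 libraries. p53 targets rose in 12 of 27 and fell in 7 (camera adjusted p = 0.0669), with FAS at 1.68, GDF15 at 1.498 and PMAIP1 at 1.06. Apoptosis regulators rose in 11 of 23 and fell in 7 (camera adjusted p = 0.404), with BCL2A1 at 1.65 and BCL2L1 at -1.09. TGF-beta response genes rose in 10 of 20 and fell in 2 (10 and 3 when adjusted over the list alone; camera adjusted p = 0.134), with INHBA at 1.10 and ID1 at -0.78. Glycolysis genes fell in 11 of 19 and rose in 2 (camera adjusted p = 0.066; adjusted p = 0.0328 without sh-Control replicate 2), with PFKL at 0.63 and PGK1 at -0.41. NRF2 targets fell in 11 of 23 and rose in 5 (camera adjusted p = 0.118), with UGDH at -1.37 and HMOX1 at 0.77. Mitochondrially encoded genes fell in 6 of 13 and rose in 0 by edgeR (camera adjusted p = 0.369; adjusted p = 0.0527 without sh-Control replicate 1), with MT-ND5 at -0.42. The share of counts from the mitochondrial chromosome was alike, 2.64% ± 0.277 in sh-Control and 2.637% ± 0.047 in sh-CBX7 (SD, n = 3 per group). Histone genes, read poorly by poly-A libraries, rose in 5 of 8 and fell in 1 (camera adjusted p = 0.118), with HIST1H2BK at 1.35. Kidney epithelial markers rose in 8 of 15 and fell in 4 (9 and 4 when adjusted over the list alone; camera adjusted p = 0.168), with MME at 0.81 and KRT7 at 1.15.

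Markers of other cell types were also examined. Of 17 immune cell markers 3 were tested, 0 rose and 2 fell in the edgeR test, with LAPTM5 going from 57.8 ± 6.03 to 26.6 ± 1.08 CPM (SD, n = 3 per group). Endothelial markers rose in 3 of 5 and fell in 0 (median 0.612, camera adjusted p = 0.122), with EGFL7 at 0.61. Fibroblast markers split 2 and 2 of 6 (camera adjusted p = 0.752), with LUM at 0.73 and COL1A1 at -1.03. In lists for which no count adjusted over the list alone is given, that count equalled the one over all genes.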

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

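The upper quartile normalization, the correction for length and GC content and the list tests without CTCTGCT genes were chosen after seeing the data. With an absolute log2 fold change of at least 1, the counts were 762 higher and 481 lower, by construction of the limit. With an estimated correlation 1 list was called in place of 14, the TNF and NF-kB list having an adjusted p = 0.0888, and fry called 26. Fry tests whether a list moves at all, not against other genes. Some lists that lost the call had an estimated correlation above the preset 0.01, such as ribosomal protein genes (0.247). It was below 0.01 for matrix (-4.83e-05), cholesterol synthesis (-0.00678), HIF (-0.016), unfolded protein response (-0.0344), MYC (-0.0254) and heat shock genes (0.00717). Correlation among members is thus not why these last lists lost the call, and what else was the cause was not tested. Fry gave the TNF and NF-kB list an adjusted p = 1.58e-05, and across the other alternatives its camera adjusted p ran from 9.35e-08 to 1.17e-06. Without CTCTGCT genes 17 lists were called, the 14 with p53 targets (adjusted p = 0.0155), apoptosis regulators (0.045) and glycolysis genes (0.0333); without sh-Control replicate 2 there were 15, with glycolysis genes (0.0328). Apart from the estimated correlation, each remaining camera setting called the 14. Other settings gave counts within 1.5 times those reported: DESeq2 called 3346 higher and 3446 lower, upper quartile normalization 4312 and 3521, and the length and GC correction 3614 and 4162. Without 1 library, 3398 to 3953 genes were higher and 3584 to 4082 lower, the most without sh-Control replicate 1. The CBX7 log2 fold change in these fits lay between -0.775 and -0.649. With the replicate number as a block, 3972 genes were higher and 4126 lower. Libraries with the same number shared deviations at correlations of 0.055, 0.061 and 0.035, and those with different numbers at -0.047 to -0.009. Each library thus correlated best with its own number, but weakly, and whether the numbers mark pairs cannot be told. The unpaired fit was kept because the labels give no shared batch for the numbers. Of 144 named genes, 140 kept direction and call under each alternative fit. CORO1A, PECAM1, ROBO4 and MT-ND4L lost the call under at least 1, including leaving out single libraries, and 0 called genes reversed. A change of sign in an uncalled gene was not counted, and the minimum log2 fold change of 1 was not applied to named genes. Depth limits the precision of low genes: the SE of the log2 fold change was 0.43 for TNFSF15 and 0.05 for ACTB.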

Other observations

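The tests on CTCTGCT, on 3' UTR length and GC content, on CBX7 near matches, on Polycomb classes, on TCGGAGA as a seed site, on immune transcripts, on MRTF and SRF targets, on list members without TCGGAGA or CTCTGCT and on the length and GC trend in lists were chosen after seeing the data; that on splits of the libraries was not. Genes that actin dynamics control through MRTF and SRF, with actins themselves left out, were collected into a list after ACTA2 had been seen to rise, and its members named here, like SPOCD1, were picked after their values were seen. Of 25 tested members 18 rose and 4 fell, with a median log2 fold change of 0.603 (camera p = 3.83e-05; p = 0.0197 with an estimated correlation). The tropomyosin TPM4 rose from 420.4 ± 11.7 to 2115 ± 73.8 CPM (SD, n = 3 per group; log2 fold change 2.33), the myosin light chain MYL9 by 2.25, the actin-binding protein CALD1 by 1.43 and SRF itself by 0.60, while FHL2 had -0.79 and ZYX -0.73. A candidate explanation for the rise of ACTA2 while ACTB and ACTG1 fell is MRTF and SRF activity after loss of cytoplasmic actin; the median of 0.603 goes with it, but 5 members were also in lists already examined, and EGR1, itself an SRF target, fell.

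The 7-base sequence CTCTGCT marked genes that fell. In 3' UTRs it had the lowest z of the 16363 7-mers held by at least 20 genes (-13.95, against -4.62 at the lowest in 100 permutations), and it came first in a random part of the genes and again in the rest. It also had the lowest z among 7-mers of coding sequences (-10.17) and whole transcripts (-12.67). In that remainder, the mean log2 fold change of genes with it minus that of genes without was -0.203 (SE 0.0192 over genes). The motif had first been seen over all genes, so that part was not wholly unseen. The difference was -0.178 (SE 0.0145) with 1 site, -0.233 (SE 0.0315) with 2 and -0.278 (SE 0.0583) with 3 or more, and no trend over these was tested. The motif was held by 51.1% of genes that fell by at least 1, against 21.3% of all genes examined. Over all genes examined the difference was -0.194 (SE 0.0134) before and -0.195 (SE 0.0131) after a fit on 3' UTR length and GC content, which argues against those properties as the whole cause. This is the pattern expected of a small RNA with the matching seed, so such an RNA may lower many transcripts in the sh-CBX7 libraries; the labels do not give the hairpin's sequence.

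The sequence occurs in CBX7 itself, and the 16-base CBX7 window AGGAGAAGCTCTGCTT (GRCh38 chromosome 22, 39134691 to 39134706, minus strand, exon 5, coding sequence) ranked 15 of 4012 CBX7 windows by the mean fall of near-match genes, the best of 20 windows with the motif. The match of ACTB and ACTG1 had been noticed before this ranking, and without them the window ranked 49, outside the lowest 1% (40.1 windows). The window had near matches in 43 genes and the 14 windows above it in 3 to 11. Weighted for the number of genes it ranked 2 (z -6.21, against -3.85 at the lowest of windows that do not overlap it), and without the actins also 2 (z -4.48 against -3.86). The weighted rank without the actins was run after the other ranks had been seen, so it does not settle what the unweighted rank left open. Counted from 1 at the window's 5' end, ACTB (chromosome 7, 5528430 to 5528445) and ACTG1 (chromosome 17, 81511337 to 81511352) differ by C11G and T16A, LGALS3BP by A1T and T15C and HECTD3 by T12C and T16A, all in coding sequence, while SEC22A matches exactly in its 3' UTR (chromosome 3, 123271814 to 123271829). Of the 10264 genes with a transcript and a mean of at least 5 CPM, CBX7 left out, 24 fell by at least 2, and these 5 are among them, where 0.10 near matches are expected by chance (Fisher's exact p = 4.07e-08, two-sided, on a window picked for its rank); without the actins it was 3 of 22 (Fisher's exact p = 8.65e-05). In 4 of the 5 a mismatch lies inside the motif. Of all 43 near-match genes 25 were called lower and 8 higher, with a median log2 fold change of -0.367; SPOCD1, with 2 mismatches, rose by 2.96. Whether near matches of the CBX7 hairpin lowered ACTB and ACTG1 thus stays open, as does loss of Polycomb repression. For the latter, HOX genes gave camera adjusted p = 0.0669 and developmental transcription factors 0.722. These lists ask whether Polycomb target classes rose, so they cannot decide why the actins fell. CBX7 fell less than these genes, and no second hairpin or rescue was analysed here.

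Genes with TCGGAGA in the 3' UTR lay above the others by 0.188 (SE 0.0464 over genes), and TCGGAGA had the highest z of the ranked 7-mers (5.13), although permutations reached 5.65. It is complementary to bases 2 to 8 of a non-targeting control sequence in common use, TTCTCCGAACGTGTCACGT, whose use here the labels do not state. Which strand of such a control would act is not known here, and no result is given for a site of the opposite strand. It also had the highest z of 7-mers in coding sequences (6.49) and whole transcripts (6.18), where zinc finger genes were not left out and no permutations were run. With zinc finger genes left out, its z in 3' UTRs was 3.03 at rank 14 in the remaining part of the genes, so a seed effect of the control hairpin can be neither shown nor excluded.

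The rise of TNF, NF-kB and interferon genes was set against a pair of technical explanations. The 90 of 99 members without TCGGAGA in the transcript had a median log2 fold change of 0.94 (SD 0.884 over members). For the 46 of 53 such interferon genes it was 1.378 (SD 0.813), which argues against relief from the control hairpin through this site in their own transcripts. An indirect effect through other genes that hold the site was not tested for either list. For the 44 of 46 such TNF and NF-kB targets it was 0.642 (SD 0.804), against 0.665 over all 46. That argues against sites in the members' own transcripts as the whole cause of this list's rise, although single members varied widely. RNA from immune cells would bring their abundant transcripts, but 3 of 5 such transcripts (PTPRC, TYROBP and LYZ) stayed under 1 CPM in each sh-CBX7 library, and LAPTM5 fell. A response to the hairpin RNA itself and an effect of lower CBX7 remain open and were not tested.

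The fall of ribosomal protein genes was not removed by sequence properties. After the trend with transcript length and GC content was removed, the ribosomal protein median was -0.645 (SD 0.323 over members), and the 66 of 75 members without CTCTGCT had a median of -0.642 (SD 0.32). For oxidative phosphorylation genes these medians were -0.336 (SD 0.379) and, over 33 of 41 members, -0.289 (SD 0.263), against -0.289 over all 41. Neither step made that fall smaller, which argues against either property of the members' own transcripts as its whole cause. The SDs give the spread over members, not the error of a median. Slower growth, as the lower cell cycle genes would go with, was not tested apart from lower CBX7.

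The real grouping gave 7766 called genes in the edgeR test and the highest of the other splits 0; at an unadjusted p under 0.05 these were 8446 and at most 237, and no other tool was run on the splits. Of the 10 splits of the 6 libraries 1, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each other split put libraries of both groups on each side, so the difference between groups widened the spread within a side. Few calls in those splits were thus fixed in advance, and they do not measure how many genes are called without a real difference.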
